A study of Homo sapiens with 6 samples.

How the data were processed

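Total RNA from cells that the labels name HTR-8, a placental extravillous trophoblast line, was measured on 6 Affymetrix arrays. Per the labels, 3 samples carried a short hairpin RNA against CSRP2BP and 3 were controls, described as independent replicates. Whether each replicate was a separate culture, infection or extraction was not given in the sources used here, so p-values measure the spread between these samples. Each sample was placed in its group by its title, and no covariate was given.

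The deposited table held log2 values for 49395 probe sets on each array, and the submitters' processing notes named Affymetrix Expression Console. The log base was read from the values, which ran from 2.61 to 14.7 with no zero, the span of log2 scanner readings. The method of background correction, summarisation and normalization was not given in the sources used here. The quartiles of the 6 arrays were nearly equal, with medians between 6.74 and 6.77, so a change in total RNA per cell could not be measured. A probe set also compresses large changes of dim genes, because signals level off at the background. No detection call was used, and the 23 background control probe sets had a median of 3.56. For arrays, precision is limited by their number, 3 per group.

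Probe sets were named from the platform annotation, with symbols compared through Entrez identifiers with RefSeq genes of the GRCh38.p14 assembly, used for names and gene order only. Of the probe sets, 44994 had 1 gene symbol, 1832 had several and 2569 were unlisted, of which 96 were control probe sets. Of the single-gene probe sets, 44967 matched by Entrez identifier. Each of 18132 genes took its probe set with the highest mean over the 6 arrays, and 11735 genes had more than 1. Probe sets with several genes or none were left out of the gene tests. The targeted gene is listed under its current symbol, KAT14.

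Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided) on the log2 values, with Benjamini-Hochberg adjustment over all 18132 genes and a threshold of 0.05. Genes past it with a log2 difference of at least 1 were counted too. Values are means ± SD over 3 arrays, and log2 differences are knockdown minus control with limma's standard error (SE). An exact permutation test of 3 against 3 arrays cannot go below 0.1, so none was used for single values. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over 31 lists, and again with a correlation estimated from the data. Members past the threshold were counted over all genes and adjusted over the list alone.

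The tests, the lists and the rule for named genes were fixed before the data were examined. The lists covered the ATAC and SAGA complexes, other histone acetyltransferases, epithelial and mesenchymal genes, matrix proteases and their inhibitors, integrins and focal adhesion, and markers of extravillous trophoblast, cytotrophoblast, syncytiotrophoblast, stromal fibroblasts, endothelium and leukocytes. They also covered S phase, mitosis, interferon, NF-kB and cytokine, TGF-beta, Wnt, YAP and TEAD, hypoxia and angiogenic genes. The remaining lists were the integrated stress response, endoplasmic reticulum (ER) chaperones, cholesterol synthesis, p53 targets, apoptosis, cytosolic ribosomal proteins, ribosome biogenesis, immediate early genes, and heat shock and oxidative stress. Of 939 distinct genes fixed, 880 were measured by a probe set of their own. The text names the targeted gene, the 12 genes with the highest and the 12 with the lowest log2 difference among genes past the threshold with separate groups, and up to 2 rising and 2 falling members of each list. XIST, Y-linked genes, placeholder names and probe sets with several genes were passed over.

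The gene fit was tested on simulated data with 18132 genes, 50 changed at each size. It recovered 36% of changes of 0.3 log2 units, 86% at 0.5, 98% at 1 and 100% at 2, with 14 false calls among 174. The simulated noise was independent between genes and alike on all arrays, and far fewer genes changed than were called in the data. These shares therefore check the fit and do not give its error rates in the data. Alternatives were quantile normalization, subtraction of each array's median, a filter on dim genes, the mean of a gene's probe sets, the replicate number as a block, a variance prior with trend and robust estimation, no variance shrinkage, array weights, each array left out in turn, all probe sets, and other thresholds. Scaling of each array to the mean of its hybridization or polyA spike-ins was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.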

Results

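Gene expression was measured in cells labelled as the extravillous trophoblast line HTR-8, with a short hairpin RNA against CSRP2BP and in control cells, with 3 arrays in each group. CSRP2BP, now named KAT14, is a subunit of the ATAC histone acetyltransferase complex. Values of all probe sets correlated across genes, which are not independent replicates, at 0.996 to 0.999 within the controls and 0.998 to 0.999 within the knockdown arrays. Between the groups the correlations were 0.990 to 0.991. Control replicate 1 stood apart from the other controls, with 55 genes more than 2-fold from the rest of its group, against 2 and 2 genes for the other control arrays and 0 for each knockdown array.

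The first question was how far the targeted transcript was lowered. KAT14 fell 3.03-fold, from 8.54 ± 0.0368 in control to 6.94 ± 0.122 in knockdown (log2, SD, n = 3), which left 33.0% of the control signal. Its log2 difference was -1.60 (SE 0.07, limma adjusted p = 6.19e-06), and each of the 3 knockdown values, 7.06, 6.95 and 6.82, lay below each control value, 8.55, 8.57 and 8.50. Its other single-gene probe set fell 3.05-fold, from 7.59 ± 0.146 to 5.98 ± 0.0205. The third probe set, shared with PET117, had a log2 difference of -0.19 that did not pass the threshold over all probe sets (limma adjusted p = 0.0781).

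**Figure D1:**
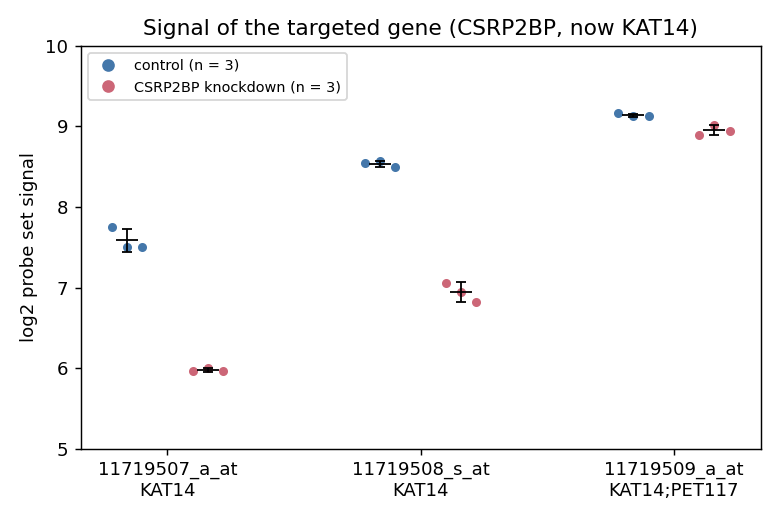
Log2 signal of the 3 probe sets that match CSRP2BP (KAT14), for each control array and each knockdown array; points are arrays and bars are means ± SD (n = 3). The 2 probe sets of KAT14 alone are lower on every knockdown array than on every control array, by 1.61 and 1.60 log2 units on average, and the probe set shared with PET117 differs by less.

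The second question was which genes differed between knockdown and control cells. FAM9B, a testis-expressed gene, had the largest measured rise, 22.2-fold, from 4.07 ± 0.122 to 8.54 ± 0.123 (log2, SD, n = 3). It was followed by SERPINB7, a serine protease inhibitor, which rose 16.1-fold, and DIO2, the deiodinase that activates thyroid hormone, which rose 11.6-fold. FAM9B and SERPINB7 started near the background, so the order of their rises is not settled. PAGE1, a cancer-testis antigen, had the largest measured fall, 44.3-fold, from 10.3 ± 0.0869 to 4.79 ± 0.156. Next was PCOLCE2, an enhancer of procollagen processing, at 41.2-fold lower. PCOLCE2 ended near the background, so which of these genes fell more is not settled. RARB, a nuclear retinoic acid receptor, fell 21.6-fold, from 10.1 ± 0.168 to 5.69 ± 0.131.

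The other genes with the highest log2 differences were LRRC17 (3.32), the intracellular fibroblast growth factor homologue FGF13 (2.95), TAFA2 (2.85), the presynaptic scaffold gene PCLO (2.52), LTF, which encodes lactoferrin (2.37), DHRS2 (2.30), the embryonic globin HBE1 (2.29), the transporter ABCA8 (2.24) and VSTM1 (2.21). Those with the lowest were TMEM98 (-4.29), KLHL4 (-3.81), MS4A6E (-3.81), SPP1, which encodes the secreted matrix protein osteopontin (-3.52), the glycerol-3-phosphate acyltransferase GPAT3 (-3.41), DIPK1A (-3.39), CLIC2 (-3.39), TPD52 (-3.31) and the glycosyltransferase B3GNT5 (-3.30). The limma adjusted p of these 24 genes was at most 0.00186, for ABCA8, and no probe set of any of them was past the threshold in the other direction. In control replicate 1, ABCA8 was at 7.24 against 6.10 and 5.83 in the other controls, and MS4A6E was at 10.30 against 8.97 and 8.92. Without variance shrinkage the adjusted p of ABCA8 was 0.0557. FAM9B, SERPINB7, PCOLCE2, DIPK1A and B3GNT5 lay within 1 log2 unit of the background in their dimmer group, so the fold of these 5 is limited by the floor of the array. FAM9B, PAGE1 and HBE1 belong to families of similar genes, which a probe set can share.

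**Figure D2:**
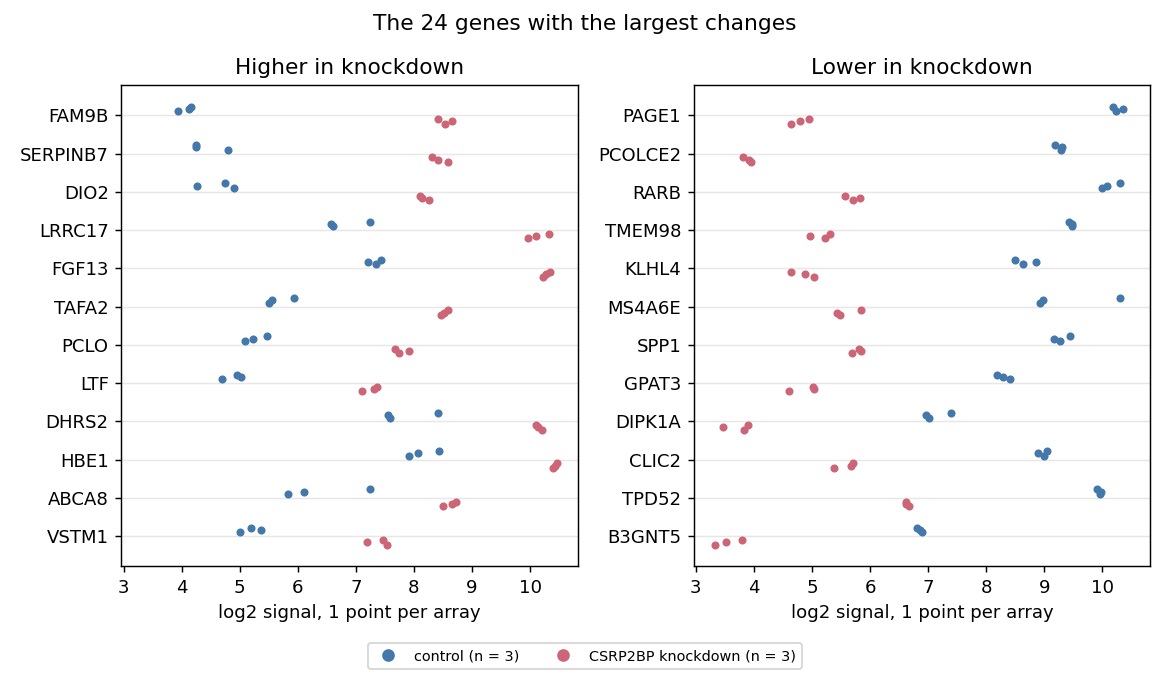
Log2 signal of the 12 genes with the highest and the 12 with the lowest log2 difference among genes past adjusted p 0.05, with 1 point per array, control and knockdown in separate colours (n = 3 each). The groups do not overlap for any of the 24 genes; FAM9B rose from 4.07 to 8.54 and PAGE1 fell from 10.3 to 4.79.

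In all, 3124 of 18132 genes (17.2%) passed the threshold in limma, 1503 higher and 1621 lower in knockdown. Most changes were small, with a median size of 0.41 log2 units, and 2054 of the called genes changed by less than 0.5. A change of at least 2-fold was seen in 278 genes, 86 higher and 192 lower. The 3 knockdown values lay wholly on 1 side of the 3 control values in 6184 genes (34.1%), where chance gives 10%. Changes are relative to the common level of each array. With each array scaled to its hybridization spike-ins, or to its polyA spike-ins, the median of all genes moved from 0.01 to -0.14 or -0.19. The calls then split into 695 higher and 4326 lower, or 310 higher and 2414 lower. The count was 2035 without control replicate 2, 1983 without knockdown replicate 1 and 4326 without control replicate 1.

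In the lists of heat shock and oxidative stress, cholesterol synthesis and integrated stress response genes, each member past the threshold over all genes was lower in knockdown, though most members did not pass. Of 28 measured heat shock and oxidative stress genes, 9 fell and 0 rose, and 10 were lower when adjusted over the list alone. The aldo-keto reductase AKR1B10 fell 4.14-fold, from 9.12 ± 0.267 to 7.07 ± 0.148, and SLC7A11, the cystine transporter, fell 2.55-fold, from 10.1 ± 0.0652 to 8.77 ± 0.0954 (log2, SD, n = 3). The other members that fell, listed after their values were seen, were AKR1C3, HMOX1, GCLM, ME1 and PGD, enzymes of redox and NADPH metabolism, and the chaperones HSPA1B and HSPH1. The list was lower than other genes in camera (adjusted p = 3.11e-05, and adjusted p = 0.270 with an estimated correlation). The estimated correlation, 0.0096, lay below the preset 0.01, so a larger correlation does not account for the higher adjusted p. Its median member lay at -0.11 in control replicate 1 against the other controls. Probe sets can share signal between AKR1C3 and its paralogs, and between HSPA1B and HSPA1A.

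Of 19 measured cholesterol synthesis genes, 7 fell and 0 rose, and 10 were lower when adjusted over the list alone. DHCR7, a late enzyme of the pathway to cholesterol, fell 1.79-fold, from 9.45 ± 0.428 to 8.62 ± 0.0357, and SQLE, squalene epoxidase, fell 1.61-fold, from 10.8 ± 0.185 to 10.1 ± 0.0651 (log2, SD, n = 3). The list median was -0.36, and camera called it lower (adjusted p = 3.11e-05, and adjusted p = 0.549 with an estimated correlation). In control replicate 1 the median member lay 0.32 log2 units above the other controls, and without that array the list was still called lower (adjusted p = 6.43e-05 in camera). Relative to the mean of the 6 arrays, the mean member was at 0.43 in control replicate 1, against 0.08 and 0.04 in the other controls. It was at -0.20 to -0.17 in knockdown, so the difference is smaller without control replicate 1. DHCR7 lost its call without knockdown replicate 1 (limma adjusted p = 0.0542) or without knockdown replicate 2 (limma adjusted p = 0.0552).

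Of 34 integrated stress response genes, targets of ATF4 and CHOP, 11 fell and 0 rose, against 11 lower and 1 higher when adjusted over the list alone. PHGDH, which begins serine synthesis, fell 2.15-fold, from 9.28 ± 0.0778 to 8.18 ± 0.113 (log2, SD, n = 3), and SLC7A11 is also on this list. Camera called the list lower (adjusted p = 0.000526, and adjusted p = 0.549 with an estimated correlation). Its median member lay 0.09 log2 units higher in control replicate 1 than in the other controls, and without that array the list was still called (adjusted p = 0.00992 in camera). Of 32 ribosome biogenesis genes, 4 fell and 1 rose, the same counts as when adjusted over the list alone. LYAR fell by 0.52 and PES1 by 0.51 on the log2 scale, both proteins of the nucleolus, while FBL, the rRNA methyltransferase fibrillarin, rose by 0.40. PES1 opens a run of 50 neighbouring genes with a median log2 difference of -0.24, of which 48% were called. Its fall cannot be told apart from that regional shift. The other named genes were not placed against such runs, so the same limit may hold for them. The lists were not tested without the genes of such runs. This list was lower in camera (adjusted p = 0.000236, and adjusted p = 0.823 with an estimated correlation), but not with arrays scaled to the polyA spike-ins (adjusted p = 0.0626). Its median member lay at -0.25 in control replicate 1 against the other controls.

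More p53 targets, and more YAP and TEAD targets, rose than fell after knockdown. Of 24 p53 targets, 11 rose and 2 fell, with 12 higher and 2 lower when adjusted over the list alone. SPATA18, a gene of mitochondrial quality control, rose 1.71-fold, from 7.27 ± 0.248 to 8.05 ± 0.0131 (log2, SD, n = 3), and GADD45A, a growth arrest gene, rose 1.53-fold, by 0.61 on the log2 scale (SE 0.07). GDF15, a stress-induced cytokine, and PMAIP1, a pro-apoptotic BCL2 family gene, fell by 0.37 and 0.21 on the log2 scale. Camera called the list higher (adjusted p = 0.00158, and adjusted p = 0.549 with an estimated correlation). The list was fixed on the understanding that the line carries SV40 large T antigen. Activity of p53 itself was not measured. The median p53 target lay 0.18 log2 units higher in control replicate 1 than in the other controls. GDF15 lost its call on leaving out any of the 3 knockdown arrays (limma adjusted p = 0.0516 to 0.0697). PMAIP1 lost its call without control replicate 2, control replicate 3 or any knockdown array (limma adjusted p = 0.0619 to 0.124).

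Of 25 YAP and TEAD targets, 10 rose and 3 fell, with 12 higher and 3 lower when adjusted over the list alone. IGFBP3, a carrier of insulin-like growth factors, rose 2.56-fold, from 6.64 ± 0.0464 to 7.99 ± 0.0629, and the receptor tyrosine kinase AXL rose 1.55-fold, from 12.7 ± 0.0708 to 13.3 ± 0.0603 (log2, SD, n = 3). WWC1 and LATS2, members of the Hippo pathway, fell by 0.95 and 0.45 on the log2 scale. Camera called the list higher (adjusted p = 0.0052, and adjusted p = 0.418 with an estimated correlation). The estimated correlation, 0.0064, lay below the preset 0.01, so a larger correlation does not account for the higher adjusted p. YAP1 itself, on the cytotrophoblast list, fell 2.14-fold, from 10.4 ± 0.157 to 9.34 ± 0.0659. With the mean of its probe sets, WWC1 had an adjusted p of 0.107 in limma.

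**Figure D3:**
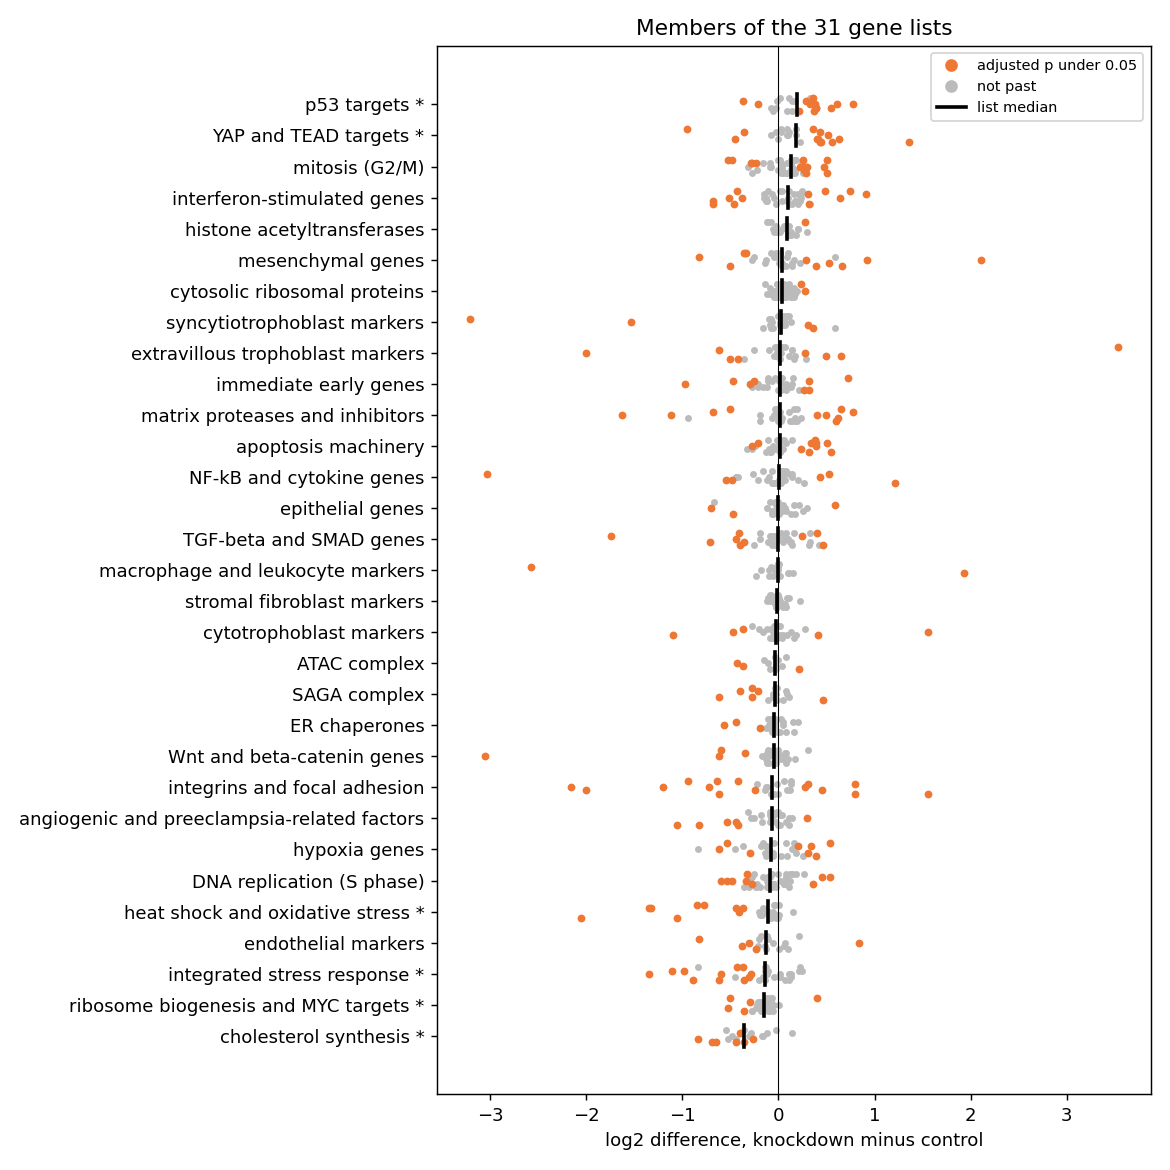
Log2 difference, knockdown minus control, of each measured member of the 31 gene lists; orange points passed adjusted p 0.05 in limma over all genes, grey points did not, black bars are list medians, and an asterisk marks the 6 lists past adjusted p 0.05 in camera with the preset correlation. The lowest list median, -0.36, is that of cholesterol synthesis and the highest, 0.19, that of p53 targets.

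**Figure D4:**
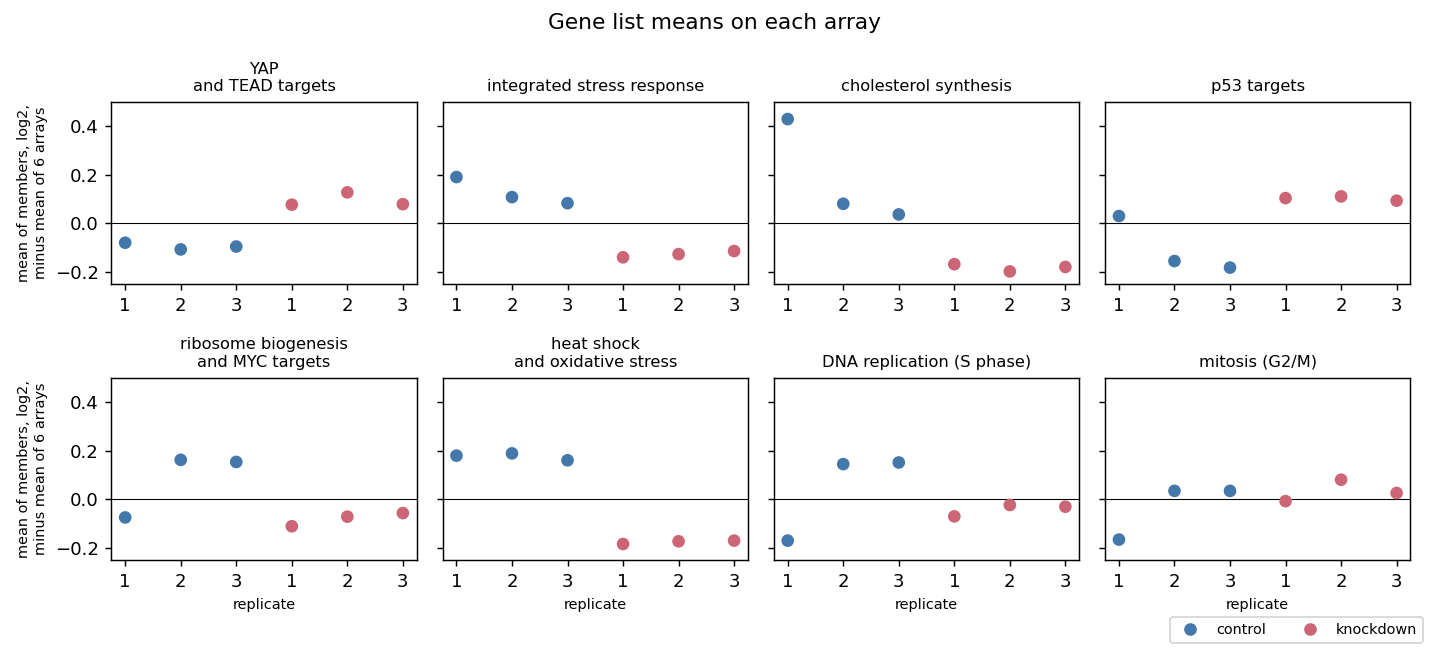
Mean of the members of 8 gene lists on each array, in log2 units relative to the mean of the 6 arrays: the 6 lists called by camera, S phase and mitosis. For mitosis genes the 3 knockdown arrays run from -0.01 to 0.08, around control replicates 2 and 3 at 0.03, and they lie closer together in the other lists. Control replicate 1 lies apart from control replicates 2 and 3 for cholesterol synthesis, p53 targets, ribosome biogenesis, S phase and mitosis genes.

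Integrin genes went both ways. Of 28 integrin and focal adhesion genes, 6 rose and 9 fell, with 6 higher and 10 lower when adjusted over the list alone, and camera did not call the list (adjusted p = 0.269). ITGA2 and ITGA1, collagen-binding integrin subunits, both fell, ITGA2 4.46-fold and ITGA1 from 6.09 ± 0.474 to 4.09 ± 0.248, within 1 log2 unit of the background (log2, SD, n = 3). ITGB4, the hemidesmosomal subunit, rose 2.94-fold, from 6.55 ± 0.267 to 8.10 ± 0.15, and the focal adhesion protein gene TNS3 rose 1.73-fold. These genes were not placed against regions of neighbouring genes that shifted together, so a regional shift cannot be told apart for them. The median member of this list lay 0.13 log2 units higher in control replicate 1 than in the other controls.

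Among 31 mesenchymal genes, 6 rose and 4 fell (7 and 4 when adjusted over the list alone, camera adjusted p = 0.498). POSTN, which encodes the matrix protein periostin, rose 4.31-fold, while COL6A1 and the collagen cross-linking enzyme LOX fell 1.78-fold and 1.42-fold. Among 27 epithelial genes, 1 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.997). Of these 27 genes 8 lay within 1 log2 unit of the background and 4 in the upper quartile of all genes. This limits the change that could be seen. KRT8, a keratin, rose 1.51-fold and the tight junction gene CLDN1 fell 1.63-fold. Among 39 matrix protease and inhibitor genes, 6 rose and 4 fell (6 and 5 when adjusted over the list alone, camera adjusted p = 0.649). The metalloproteinases ADAMTS1 and MMP16 fell 3.10-fold and 2.18-fold, and ADAM19 rose 1.57-fold, with a limma adjusted p of 0.229 when the mean of its probe sets was used.

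Markers of the trophoblast lineages did not move as groups. Of 27 extravillous trophoblast markers, 4 rose, DIO2 the most, and 4 fell, ITGA1 the most, the same counts as when adjusted over the list alone (camera adjusted p = 0.866). Of 27 cytotrophoblast markers, 2 rose and 3 fell (3 and 3 when adjusted over the list alone, camera adjusted p = 0.709). Of 24 syncytiotrophoblast markers, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.956). TFPI2, a serine protease inhibitor, fell 9.29-fold, from 8.03 ± 0.106 to 4.81 ± 0.0664, and SLC40A1, the iron exporter ferroportin, fell from 5.66 ± 0.5 to 4.12 ± 0.22, within 1 log2 unit of the background (log2, SD, n = 3). PSG4 rose by 0.36 on the log2 scale, and belongs to a family of nearly identical genes.

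Of 24 stromal fibroblast markers, 0 passed the threshold in limma, over all genes or adjusted over the list alone, and their median log2 difference was -0.01 (camera adjusted p = 0.956). Of these 24 markers 12 lay within 1 log2 unit of the background and 0 in the upper quartile of all genes, which limits the change that could be seen. Of 18 endothelial markers, 1 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.157). ROBO4, a guidance receptor of endothelium, rose 1.79-fold and the receptor gene TIE1 fell 1.30-fold. The median endothelial marker lay 0.27 log2 units higher in control replicate 1 than in the other controls, and without control replicate 3 the list was called lower (adjusted p = 0.0144 in camera, and adjusted p = 0.818 with an estimated correlation). Several endothelial genes were bright in both groups: 11 of the 18 markers had a mean in the upper quartile of all genes and 2 lay within 1 log2 unit of the background. Named after their values were seen, ECSCR was at 13.3 ± 0.0348 in control and 13.2 ± 0.0198 in knockdown, CDH5, the endothelial cadherin, at 12.3 ± 0.218 and 12.2 ± 0.0387, and PECAM1 at 12.02 ± 0.418 and 12.03 ± 0.0162 (log2, SD, n = 3). Of the 27 extravillous trophoblast markers 9 lay in that quartile and 3 near the background, of the 27 cytotrophoblast markers 7 and 6, and of the 24 syncytiotrophoblast markers 1 and 11. Transcription factor genes of the trophoblast lists were also named after their values were seen. In control, TFAP2C, ELF5 and GCM1 were at 4.18, 3.90 and 4.18, and TEAD4, GATA2 and TEAD1 at 10.23, 10.06 and 9.92. Between them lay MSX2 at 7.46, ARID3A at 7.38, GATA3 at 6.20, CDX2 at 5.94, HAND1 at 5.94, ASCL2 at 5.54 and TFAP2A at 5.47. The extravillous marker HLA-G was at 6.47, and the keratin KRT7, also on the epithelial list, at 13.5. The identity of the cells rests on the labels and was not tested. Signals of different probe sets are not on 1 scale, so these levels do not give the share of any cell type.

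Of 19 leukocyte markers, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.709). LAPTM5, a lysosomal membrane protein gene, rose 3.81-fold and LYZ, lysozyme, fell 5.98-fold. Of the 19 markers 7 lay within 1 log2 unit of the background and 1 in the upper quartile.

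Of 12 other subunits of the ATAC complex, 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.279). The acetyltransferases KAT2A and KAT2B fell 1.29-fold and 1.35-fold, and DR1 rose 1.16-fold, a call lost without any 1 of 5 of the arrays, control replicate 1 being the exception (limma adjusted p = 0.0728 to 0.101). Of 17 subunits of SAGA, the sister complex, 1 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.210). The deubiquitinase USP22 and TADA1 fell 1.53-fold and 1.32-fold. The named ATAC and SAGA genes were not placed against regions of neighbouring genes that shifted together. A regional shift therefore cannot be told apart from a change of the complexes. Of 22 other histone acetyltransferase genes, 1 rose over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.190).

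Cell cycle genes were mixed, and control replicate 1 stood apart in them. Of 51 S phase genes, 3 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.157). The DNA ligase LIG1 rose 1.37-fold and the polymerase subunit POLE2 fell 1.45-fold. Neither gene was placed against regions of neighbouring genes that shifted together, so a regional shift cannot be told apart for them. The median S phase gene lay at -0.32 in control replicate 1 against the other controls, and without that array the list was called lower in knockdown (adjusted p = 1.13e-05 in camera, and adjusted p = 0.468 with an estimated correlation). Of 54 mitosis genes, 9 rose and 5 fell (13 and 5 when adjusted over the list alone, camera adjusted p = 0.135). BIRC5, survivin, and the chromatin protein HMGB2 rose 1.42-fold each, and the mitotic kinase PLK1 fell 1.44-fold. The median mitosis gene lay at -0.21 in control replicate 1, and the list was called higher without control replicate 2 (adjusted p = 0.0174 in camera) or control replicate 3 (adjusted p = 0.0298 in camera). With an estimated correlation these were adjusted p = 0.803 and adjusted p = 0.897.

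Among signalling lists, PTGS2, the inducible cyclooxygenase, fell 8.19-fold, from 8.68 ± 0.21 to 5.64 ± 0.166, and SFRP1, a secreted Wnt antagonist, fell 8.32-fold, from 7.67 ± 0.234 to 4.61 ± 0.00874 (log2, SD, n = 3). Of 34 NF-kB and cytokine genes, 3 rose and 3 fell (4 and 5 when adjusted over the list alone, camera adjusted p = 0.822), and TNFAIP2 rose 2.32-fold. Of 29 Wnt genes, 0 rose and 4 fell (0 and 3 when adjusted over the list alone, camera adjusted p = 0.179). Of 37 TGF-beta and SMAD genes, 3 rose and 6 fell (4 and 8 when adjusted over the list alone, camera adjusted p = 0.709). The BMP antagonist GREM1 fell 3.35-fold and TGFBR2, a TGF-beta receptor, rose 1.38-fold. Of 40 interferon-stimulated genes, 6 rose and 6 fell (12 and 6 when adjusted over the list alone, camera adjusted p = 0.269). IFI6 rose 1.89-fold and IFIT2 fell 1.60-fold. Of 30 immediate early genes, 4 rose and 4 fell (5 and 5 when adjusted over the list alone, camera adjusted p = 0.997), ZFP36 rising 1.64-fold and ETV4 falling 1.97-fold.

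Of 29 angiogenic and preeclampsia-related factors, 1 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.0933). PGF, placental growth factor, rose 1.23-fold, and HMOX1, heme oxygenase, fell 2.08-fold. This list was called lower without control replicate 3 (adjusted p = 0.0298 in camera, and adjusted p = 0.573 with an estimated correlation). Of 30 hypoxia genes, 5 rose and 3 fell (5 and 4 when adjusted over the list alone, camera adjusted p = 0.709), HK2, a hexokinase, falling 1.54-fold. Of 32 apoptosis genes, 8 rose and 2 fell (8 and 4 when adjusted over the list alone, camera adjusted p = 0.697), and the death receptor gene FAS rose 1.46-fold. Of 24 ER chaperone genes, 0 rose and 3 fell (0 and 2 when adjusted over the list alone, camera adjusted p = 0.269), WFS1 falling 1.49-fold. Of 64 cytosolic ribosomal protein genes, 2 rose and 0 fell, with 0 past when adjusted over the list alone (camera adjusted p = 0.117). That list was called higher without control replicate 1 (adjusted p = 0.0242 in camera, and adjusted p = 0.851 with an estimated correlation).

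With arrays scaled to the hybridization spike-ins, DR1, SDC1, KDM4B, PGF, RPL18, RPL38, JUN and NCOA1 were not past the threshold (limma adjusted p = 0.0521 to 0.506). Scaled to the polyA spike-ins, 21 named genes were not past it (limma adjusted p = 0.0925 to 0.954), among them these 8 and LIG1, BIRC5, HMGB2, TGFBR2, FAS, FBL and PSG4. The polyA spike-ins had an SD of 0.176 in knockdown against 0.0183 in control, and scaling to them adds this spread to the genes. Without variance shrinkage, COL6A1, SLC40A1, BIRC5, PLK1, HK2, DHCR7 and GDF15 were not past the threshold (adjusted p = 0.0501 to 0.132 in the linear model of limma). With an estimated correlation, 0 of the 31 lists were called by camera, the lowest adjusted p being 0.270. For heat shock and oxidative stress and for YAP and TEAD targets the estimated correlations, 0.0096 and 0.0064, lay below the preset 0.01. A larger correlation therefore does not account for the lost calls of these lists. Camera with an estimated correlation thus differs from the preset setting in more than the correlation, and its lost calls do not measure correlation alone. The rest of the lists called with the preset correlation had estimates of 0.105 to 0.725. How far these correlations account for their lost calls was not tested. The median, the mean and the direction in camera differed in sign for 5 lists that were not called: epithelial genes, matrix proteases, syncytiotrophoblast markers, NF-kB and immediate early genes.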

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

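The tests of a signal offset, of each explanation for control replicate 1 and of both explanations for neighbouring genes were chosen after the results were seen. Some of the strongest signals lay outside the gene tests. The unlisted probe set 11762907_at rose by at least 9.73 log2 units, from 3.58 ± 0.142 to 13.3 ± 0.157 (SD, n = 3). The unlisted probe set 11757493_s_at had a log2 difference of -6.68, from 10.7 ± 0.298 to 3.99 ± 0.0464. The dimmer level of both lay within 1 log2 unit of the background median of 3.56, so these differences are lower bounds of the change. In limma over all probe sets, 341 unlisted probe sets and 236 probe sets of several genes passed adjusted p 0.05. The hybridization spike-ins, 11.1 ± 0.0343 in control and 11.3 ± 0.031 in knockdown, were 0.15 log2 units higher in knockdown. The polyA spike-ins were 0.20 higher (SE 0.10), with knockdown replicate 2 the highest at 8.51 against 8.18 and 8.24 in the other knockdown arrays. Calls lost under scaling to them can therefore reflect this spread as well as an offset.

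Of the 3124 calls between knockdown and control, 77 were higher and 155 lower past 1.5-fold in treat, which argues against a signal offset between the arrays, moving all genes 1 way, for these 232. Array medians differed by at most 0.03 log2 units, so calls in both directions were likely beforehand and this test weighs little. The hybridization spike-ins were 0.15 higher in knockdown (SE 0.03), where an offset lowering all signals would have lowered them, which argues against it for the other 1466 lower calls. Of the other 1426 higher calls 43.3% were kept with arrays scaled to the hybridization spike-ins and 15.8% with arrays scaled to the polyA spike-ins, so an offset cannot be told apart for these as a group. Of the 10 splits of the 6 samples, 1 (the real one) gave as many calls and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. Windows of 50 neighbouring genes shifted beyond shuffled gene orders held 21.8% of the called genes and 10.8% of all genes, so a regional difference between the 2 cell populations may account for some calls and cannot be told apart for those, while smaller regions and an effect of the knockdown stay open for all.

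Control replicate 1 stood apart from the other controls, with 55 genes over 2-fold away. Over the 63 genes changed at least 4-fold, it lay a median 0.448% of the way to the knockdown level (95% bootstrap interval -8.09 to 4.33), which argues against knockdown RNA making up over 5% of that sample. The median was 1.71% for higher genes and -9.47% for lower genes. The interval comes from resampled genes, which are not independent replicates of control replicate 1. Its S phase genes had a median shift of -0.32, below the 2.5th percentile (-0.07) of 10000 random lists matched on expression, but 13 of 29 lists outside the cycle also lay outside the range of theirs, cholesterol synthesis at 0.32 and endothelial markers at 0.27, so a slower cycle in that culture cannot be told apart. Its 3' minus 5' difference was 1.22 for ACTB, above the other arrays, but within their range for GAPDH, so lower RNA integrity cannot be told apart. The labels give nothing that sets this array apart.

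Neighbouring genes shifted together in 19 regions, 10 higher and 9 lower in knockdown. The correlation of log2 differences between neighbours was 0.097, against at most 0.0212 in 200 shuffled orders, which argues against a chance order of genes. In these regions 87.5% of 1084 expressed genes had the region's sign, against 82.6% at the 95th percentile of the most shifted windows of shuffled orders, and a copy number difference between the 2 cell populations is a candidate explanation. The comparison is weak, because regions were picked for their shift and shuffled windows came close. Regulation over long stretches of chromatin was not tested and stays open, as does the knockdown itself.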

How the results depend on the processing

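Every alternative was planned before the data were examined, except scaling to spike-ins and an estimated correlation for lists called only in an alternative, which were chosen after seeing the data. KAT14 kept its call under every alternative, at -1.80 to -1.54 log2 units and an adjusted p of at most 0.0049. Of 112 other named genes, 80 kept their calls in limma in each alternative planned beforehand that tested them (26 were not tested under the filter on dim genes) and 0 reversed, while 18 lost theirs on leaving out 1 array (adjusted p up to 0.149). The count of called genes was 2070 without variance shrinkage (992 higher, 1078 lower), 5861 with array weights, in which control replicate 1 weighed 0.265 (2928 higher, 2933 lower), 7841 over all probe sets (3933 higher, 3908 lower), 280 at an unadjusted p under 0.05 with 2-fold (87 higher, 193 lower) and 232 by treat against 1.5-fold (77 higher, 155 lower). With each array left out it ran from 1983 (without knockdown replicate 1) to 4326 (without control replicate 1), the higher genes from 927 to 2088 and the lower from 1056 to 2238; without control replicate 2 it was 2035. Stricter thresholds lower these counts by construction, and the cause of the others, and of those scaled to spike-ins, was not tested. Scaled to hybridization spike-ins it was 5021 (695 higher, 4326 lower), with 8 named genes no longer called, and scaled to polyA spike-ins 2724 (310 higher, 2414 lower), with 21. Genes changed at least 2-fold numbered 135 among genes above the median mean, where fewer genes were tested, and 614 among all probe sets. The 6 called lists stayed called in camera in each setting with the preset correlation, except ribosome biogenesis scaled to polyA spike-ins (adjusted p = 0.0626), and 0 lists were called with an estimated one. For heat shock and oxidative stress and for YAP and TEAD targets the estimate lay below the preset value, so a larger correlation does not account for their lost calls. With the mean of all probe sets 10 lists were called, adding endothelial, mitosis, angiogenic and ribosomal protein genes (adjusted p = 0.810, adjusted p = 0.835, adjusted p = 0.595 and adjusted p = 0.800 with an estimated correlation), and the cause was not tested. The replicate block added angiogenic genes (adjusted p = 0.813 with an estimated correlation) and the variance prior with trend ribosomal protein genes (adjusted p = 0.814). S phase genes were called lower with array weights too (adjusted p = 0.000189, and adjusted p = 0.860 with an estimated correlation). Whether replicate numbers pair the samples was not settled. Deviations of equal numbers correlated at 0.0963, 0.0332 and 0.204. Control replicate 3 and knockdown replicate 3 matched each other best, and knockdown replicate 1 matched control replicate 1 best. Control replicates 1 and 2 and knockdown replicate 2 matched an unequal number best. The replicate block gave 3161 calls. Control replicate 1 alone did not make the list calls, since without it all 6 lists were kept. The pseudocount for linear values was not run, since the table is on a log2 scale. Camera was not run without variance shrinkage. Dim genes are limited by the background of 3.56.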

Other observations

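The family test, the check without shifted windows and the description of regions were chosen after the results were seen. Among 247 families of genes sharing a symbol stem, the zinc finger genes named ZNF, many of which encode DNA-binding repressors, were the family past the threshold in enrichment for higher calls. Of 491 ZNF genes, 71 rose and 35 fell, so 14.5% rose against 8.29% of all genes (hypergeometric test, adjusted p = 0.00131). The enrichment was also past the threshold after quantile normalization (adjusted p = 0.000209), after subtraction of array medians (8.9e-05) and on leaving out each array (3.16e-06 to 0.00304). The hypergeometric test treats genes as independent, while neighbouring genes shifted together. Its p-values are therefore too small where ZNF genes lie side by side, and these repeats do not address that. Scaling to hybridization or polyA spike-ins moves all genes down together, so more ZNF genes then fell than rose, 90 against 35 or 46 against 11. With it 7.13% of ZNF genes rose against 3.83% of all genes, or 2.24% against 1.71%, and the enrichment did not pass (adjusted p = 0.0963 and 1). The family median was then -0.11 or -0.16, against -0.14 or -0.19 for all genes. Without the genes of shifted windows, 45 of 407 ZNF genes rose, 11.1% against 7.06% of all genes, and the family no longer passed (adjusted p = 0.799). The windows were chosen for their own shift and fewer genes were tested, so the lost call does not show where the enrichment came from.

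By the median over all genes of a region, 2 regions shifted the most, named after their values were seen. They were 150 genes from MBIP to ZFYVE26, where 61 genes fell and 1 rose, and 170 genes from DNAI2 to WDR45B, where 73 rose and 1 fell. Their expressed genes had median log2 differences of -0.32 and 0.28. By the median of expressed genes other regions shifted more. The lowest was -0.41, in 60 genes from ANGPT2 to SLC18A1, and the highest 0.38, in 60 genes from ROBO3 to B3GAT1. In 230 genes from PSG2 to EMC10, 75 rose and 0 fell. In 220 genes from CRYBA4 to SHISAL1, 85 fell and 9 rose. The change of a named gene inside any of the shifted regions cannot be told apart from the regional shift.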
